A study of Microhyla fissipes with 9 samples.

How the data were processed

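Whole tissue of Microhyla fissipes tadpoles was sequenced in 9 libraries, 3 each at 0 (control), 60 and 90 mg/L GBH. Per the labels' protocols, RNA was extracted with Trizol, poly-A selected and fragmented, and libraries were sequenced as paired ends on a HiSeq 2500. The authors deposited 1 table with a row per unigene and a column per library, whose values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per the labels. The values had 2 decimals and summed to between 2739365 and 3005630 per library. The assembler, clustering tool, aligner, counter, their versions and any filter are not given in the sources used here. The table had no counts, unigene lengths, sequences or gene names, and all 9 columns were matched to samples by their titles.

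Because FPKM are not counts, tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Unigenes with a mean of at least 1 FPKM over the 9 libraries were tested, 147577 in number (34.6%). A model with 1 mean per dose was fitted to all 9 libraries, with empirical Bayes moderation and a trend on mean expression. The residual degrees of freedom were 6 and the median moderated SD was 0.73 on the log2 scale. Unigenes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The same fit gave an F test over the 3 doses, and a further fit gave a slope on dose in mg/L. FPKM rather than counts means that no sampling error per value is known, and a shift in a few abundant transcripts moves all other values.

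Depth was not in the table. In low unigenes 1 fragment is worth a fixed FPKM that depends on unigene length and library size. The most frequent ratio between a library and control replicate 1 at 0.2 to 0.3 FPKM was taken as the ratio of these worths, and its inverse as the relative depth. The change of that log2 ratio up to 1.2 to 2 FPKM was taken as the fragment worth index. A difference in fragment length between libraries is 1 possible source of it, but unigene lengths were not at hand, so what the index reflects was not checked. It ranged from -0.32 in control replicate 2 to 0.365 in GBH 90 mg/L replicate 1. A lower depth leaves more low unigenes at 0, so results near 1 FPKM are the least precise.

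The procedure was tested on simulated data with the tested unigenes' own means and spreads and 200 unigenes changed. Rises and falls were pooled, and simulated values below 0 on the log2(FPKM + 1) scale were set to 0. Falls of low unigenes were therefore smaller than the stated size, and the rates may understate recovery of changes that reach it. Recovery for 60 against 0 mg/L was 0%, 0%, 10% and 42% for log2 changes of 1, 2, 3 and 4. For 90 against 0 mg/L it was 0%, 0%, 10% and 28%, and for 90 against 60 mg/L 0%, 0%, 6% and 32%. False calls numbered 5 of 31, 1 of 20 and 0 of 19, so that for 60 against 0 mg/L their share lay above the threshold of 0.05. Simulated changes of log2 1 and 2 were thus all missed, so that a unigene without a call may still have changed. The noise was drawn independently for each unigene and library, so it held no structure shared between libraries. The false calls in the simulation are therefore no error rate for the deposited data. There, other groupings of the compared libraries gave up to 108, 90 and 123 calls in the same order of comparisons.

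Libraries were compared by Pearson correlation, principal components and the share of equal values, which was at most 1.72% between any pair of libraries, so that none was taken for a copy of another. Whether replicate numbers pair the libraries was read from the correlation of deviations from the group means, with a bound of 0.1 for every pair of a comparison. The pairs of 60 and 0 mg/L gave 0.104, 0.327 and 0.113 for numbers 1, 2 and 3 and passed it, although control replicate 3 and GBH 60 mg/L replicate 1 gave 0.134. The pairs of 90 and 0 mg/L (0.106, -0.0586 and -0.173) and of 90 and 60 mg/L (0.101, -0.0681 and -0.112) did not pass. The labels do not say what a number marks. Single values per library were compared with two-sided exact permutation tests in SciPy 1.17.1, adjusted over 56 tests. The overlap of both responses was set beside 20 simulations of unchanged groups against shared controls, with noise independent between libraries. Tables were handled with pandas 2.3.3 and the R package data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9.

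Before the data were examined, 35 gene lists and a rule for naming genes had been fixed. The lists could not be tested, since no unigene carried a name. The rule then named, per comparison, the 2 unigenes with the largest rise and the 2 with the largest fall among those past the threshold whose groups did not overlap. Alternatives fixed at that point were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, the replicate number as a block, limma without a trend or with a robust spread, a 2-fold minimum, a fit to the compared groups alone, and each library left out in turn. Added after the data were examined were fits without the 3 libraries that lie apart, with a term for them, with the fragment worth index as a term, and with unigenes above 0 in all libraries, and the comparison of both doses together against control. Other groupings of the libraries were refitted in the same way, all of them for groups of 3 against 3, for 3 against 6 and within the 3 that lie apart and the other 6, and 100 drawn at random for the 3 doses.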

Results

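Gene expression was measured by RNA sequencing in tadpoles of the farmland frog Microhyla fissipes after exposure to a glyphosate-based herbicide (GBH). Glyphosate inhibits an enzyme of aromatic amino acid synthesis in plants, and commercial formulations combine it with surfactants. Tadpoles at Gosner stage 30, a hind limb bud stage, were kept for 10 days in water with GBH at 0 mg/L (control), 60 mg/L or 90 mg/L. The design placed 20 tadpoles in 1000 mL of water in each of 5 containers per dose. Each dose was represented by 3 poly-A selected libraries of whole tissue, 9 in all, and a dose of 120 mg/L was not analysed here. The labels do not say which container, or how many tadpoles, a library holds. The p-values therefore measure the spread between these libraries, which may be technical in part.

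The table listed 426250 unigenes, which are clusters of assembled transcripts, as FPKM. It paired none of them with a gene name, so unigenes are given by identifier and described by their pattern of expression. No position in a genome could be given. In each library 213161 to 256232 unigenes lay above 0 FPKM, and 89518 unigenes (21%) lay above 0 in all 9. An exact 0 was also recorded in at least 1 library for 72 unigenes with a mean above 100 FPKM, so such values are called "listed at 0". A dose listed at 0 in all its libraries adds no spread to the fit but keeps its degrees of freedom. The p-values of such unigenes may therefore be too small. Read totals were not in the table. Relative depth, recovered from the steps between low FPKM values, ranged from 0.768 in GBH 90 mg/L replicate 1 to 1.08 in GBH 90 mg/L replicate 3, with control replicate 1 set to 1.

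The first question was how the transcriptomes of exposed and control tadpoles differed as a whole. On the second principal component of log2(FPKM + 1), with 15.3% of the variance, the 3 controls lay between -217 and -165. The 6 exposed libraries lay between 2.49 and 160 on it. The first component, with 22.7% of the variance, did not follow dose. Control replicate 2, GBH 60 mg/L replicate 2 and GBH 90 mg/L replicate 3 lay at 304, 261 and 160 on it, and the other 6 libraries between -174 and -62.7. These 3 libraries are called the 3 that lie apart. Pearson correlations across unigenes were 0.687 to 0.701 among them, 0.666 to 0.754 among the other 6 and 0.560 to 0.677 between both sets. In 23743 of the 147577 tested unigenes (16.1%), all 3 lay above or all 3 below the other 6 libraries, against 8798 (5.96%) for the 3 controls and 2.38% by chance.

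**Figure D1:**
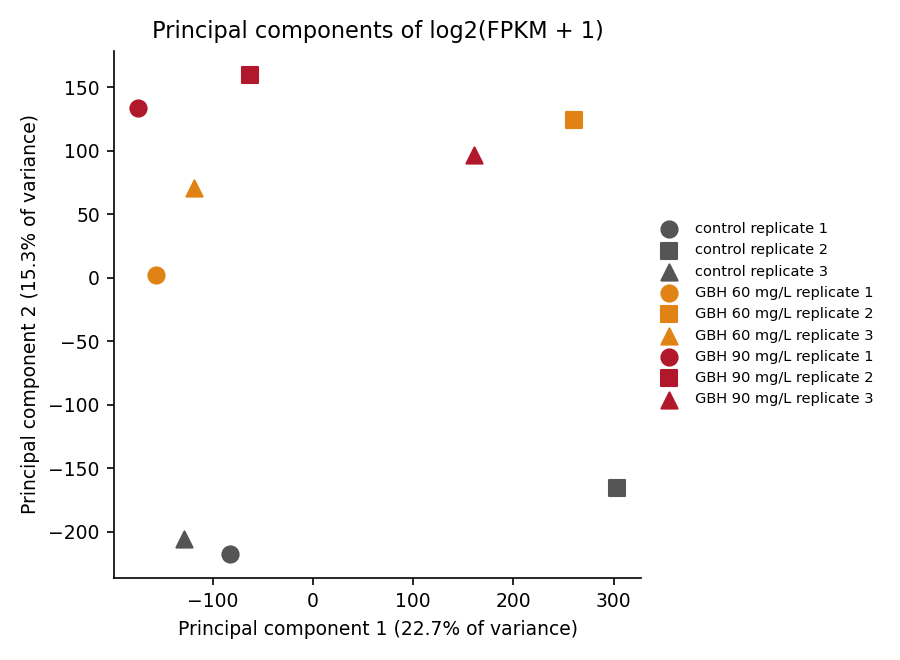
Principal components 1 and 2 (arbitrary units) of log2(FPKM + 1) over 147577 unigenes, 1 point per library, coloured by dose and shaped by replicate number. The 3 controls lie below -165 on component 2, and 1 library of each dose lies above 160 on component 1.

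Exposed libraries listed more unigenes at 1 FPKM or more than controls did. The mean was 118939 ± 4450 in controls (SD, n = 3), 136930 ± 9402 at 60 mg/L (n = 3) and 136472 ± 5404 at 90 mg/L (n = 3), and all 6 exposed libraries lay above all 3 controls. The 1000 highest unigenes held 60.5% ± 3.61 of the summed FPKM in controls (SD, n = 3), 53% ± 2.52 at 60 mg/L (n = 3) and 53.5% ± 2.40 at 90 mg/L (n = 3), again without overlap between exposed and control libraries. The 6 exposed against the 3 control libraries gave a two-sided exact permutation p = 0.0238 for both measures, the smallest this test gives, with an adjusted p of 0.267 over 56 tests. Each dose alone gave an exact p = 0.1, the smallest 3 against 3 allows. After median-ratio scaling, which sets the typical unigene equal between libraries, the counts at 1 FPKM or more were 125872 ± 1749, 129221 ± 5967 and 128802 ± 5404 (SD, n = 3 each). The groups then overlapped (exact permutation p = 0.31 for exposed against control).

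**Figure D2:**
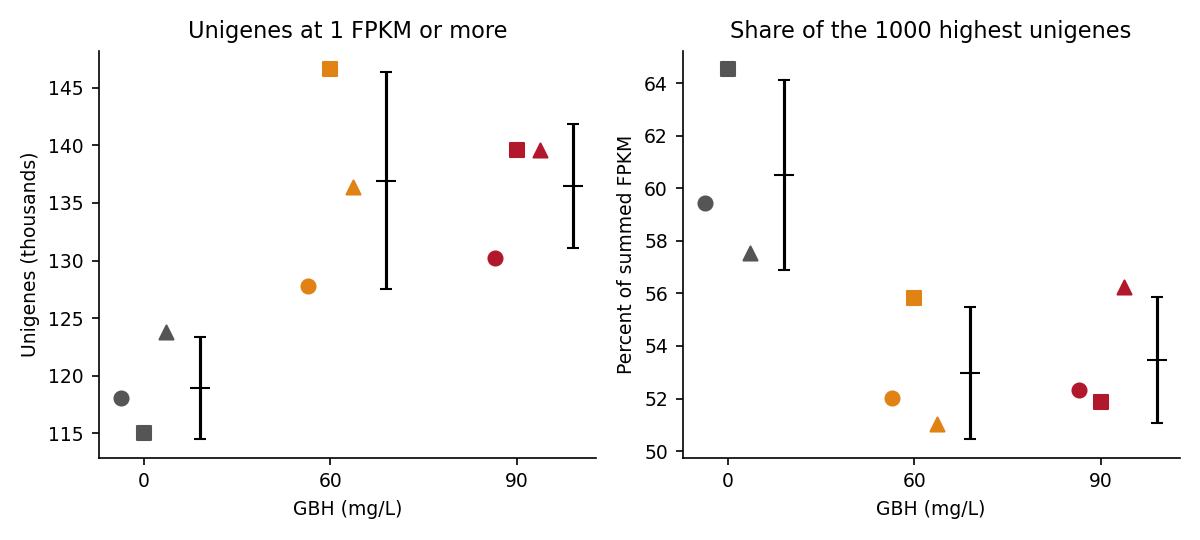
Left, unigenes at 1 FPKM or more (in units of 1000); right, percent of the summed FPKM held by the 1000 highest unigenes, by GBH dose in mg/L; points are libraries, bars mean and SD (n = 3), and axes do not start at 0. Exposed libraries hold 127830 to 146607 unigenes at this level, against 114999 to 123766 in controls.

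The comparison of 60 mg/L with control asked which transcripts change at the lower sublethal dose. In 219 unigenes expression fell and in 84 it rose, 303 in all, a balance that turned with the libraries used. Without GBH 60 mg/L replicate 1, 2 or 3, rises outnumbered falls (292 to 185, 332 to 261 and 257 to 183), and a pseudocount of 0.1 gave 102 rises and 123 falls. The unigenes that fell had held 0.993% of the summed FPKM in controls and held 0.156% at 60 mg/L, and those that rose went from 0.00888% to 0.0836%. Cluster-47276.169351 was among the abundant unigenes that fell, from 1147.81, 517.04 and 739.78 FPKM in the controls to 6.78, 0 and 1.03 FPKM (log2 difference -8.24, SE 0.72, adjusted p = 0.00562). Cluster-47276.169348 stood at 333.66, 74.81 and 246.72 FPKM in the controls and was listed at 0 in all 3 libraries at 60 mg/L (adjusted p = 0.00526). Cluster-47276.281997 rose from 1.66 ± 1.5 to 153.6 ± 108.4 FPKM (SD, n = 3 each), with a log2 difference of 5.65 (SE 0.71, adjusted p = 0.022). Cluster-47276.121244, listed at 0 in every control, stood at 57.08, 37.71 and 76.75 FPKM (adjusted p = 0.00526). These adjusted p-values come from limma with Benjamini-Hochberg adjustment, and log2 differences are on the log2(FPKM + 1) scale, which understates the change of low unigenes.

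Most unigenes that rose at 60 mg/L were listed at 0 in the controls. This held for 71 of the 84 that rose, and 119 of the 219 that fell were listed at 0 in all 3 libraries at 60 mg/L, against 11.3% of all tested unigenes with such a group. Median log2 differences were 3.43 for those that rose and -3.34 for those that fell, the smallest in size being 1.56. Only 55 of the 303 lay above 0 in all 9 libraries, 13 that rose and 42 that fell. Across all tested unigenes the groups did not overlap in 17390 (11.8%, against 10% by chance). The median of all unigenes was higher by 0.22 at 60 mg/L on the log2 scale. Under median-ratio scaling, with that median at 0, 72 unigenes rose and 294 fell, so that 19.7% of the calls were rises in place of 27.7%. The call of Cluster-47276.281997 was lost without any of control replicates 1, 2 and 3, GBH 60 mg/L replicates 1 and 3 or GBH 90 mg/L replicates 1, 2 and 3, with adjusted p-values of 0.0511 to 0.0843, and with the fragment worth index as a term (adjusted p = 0.0633), at log2 differences of 5.01 to 6.07. Without the 3 libraries that lie apart, with 2 against 2 left, Cluster-47276.121244 and Cluster-47276.169351 missed the threshold (adjusted p = 0.0516 and 0.0652) at log2 differences of 6.07 and -7.86, against 5.81 and -8.24 with all libraries. The count of 303 became 1098 without the 3 libraries that lie apart (2 against 2, with 156 of the 303 called again), 472 with a term for them, 685 without control replicate 2, 593 without GBH 60 mg/L replicate 2, 477 without GBH 60 mg/L replicate 1, 83 at a mean of at least 5 FPKM, 20 among unigenes above 0 in all libraries and 0 (9318 at an unadjusted p under 0.05) when limma was fitted to these 6 libraries alone. With the replicate number as a block, limma called 0 unigenes (10940 at an unadjusted p under 0.05), and Cluster-47276.121244, Cluster-47276.281997, Cluster-47276.169351 and Cluster-47276.169348 each had an adjusted p of 0.0574 at unchanged log2 differences. Pairs of equal number passed the bound of 0.1 in this comparison, but control replicate 3 and GBH 60 mg/L replicate 1 gave 0.134. Whether the block reflects a real pairing is therefore not established.

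At 90 mg/L, expression fell in 255 unigenes and rose in 109 against control, 364 in all. Here too the balance depended on the libraries, with 268 rises and 166 falls without GBH 90 mg/L replicate 1, 160 and 174 without replicate 2, 238 and 222 without replicate 3, and 120 and 148 with a pseudocount of 0.1. This comparison asked the same question at the higher dose. The unigenes that fell went from 1.13% of the summed FPKM in controls to 0.182%, and those that rose from 0.0157% to 0.129%. Cluster-47276.169351 fell here too, from 801.5 ± 319.9 to 1.89 ± 1.18 FPKM (SD, n = 3 each), a 424.8-fold lower mean, with a log2 difference of -8.14 (SE 0.72, adjusted p = 0.00632 by limma). Cluster-47276.169348 was listed at 0 in all 3 libraries at 90 mg/L as well (adjusted p = 0.00424). Cluster-47276.281997 showed the largest rise, from 1.66 ± 1.5 to 336.2 ± 114.1 FPKM (SD, n = 3 each), a 202.5-fold higher mean, with a log2 difference of 7.09 (SE 0.71, adjusted p = 0.00959). Cluster-47276.255942, listed at 0 in every control, stood at 24.15, 111.92 and 38.9 FPKM (adjusted p = 0.0294).

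**Figure D3:**
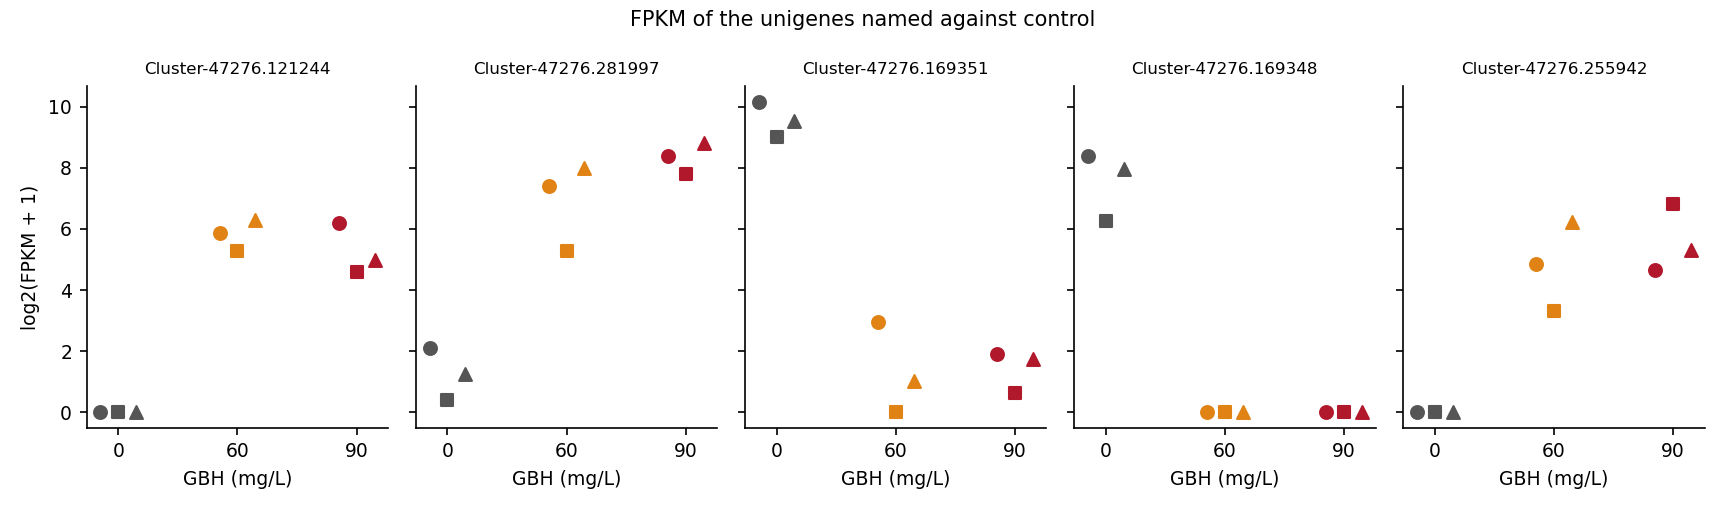
log2(FPKM + 1) of the unigenes with the largest change against control at 60 or 90 mg/L, 1 panel per unigene and 1 point per library (circle, square and triangle for replicates 1, 2 and 3), by GBH dose in mg/L. Cluster-47276.169351 and Cluster-47276.169348 are high in controls alone, and Cluster-47276.121244 and Cluster-47276.255942 are listed at 0 in every control.

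Of the 109 unigenes that rose at 90 mg/L, 83 were listed at 0 in all controls, and 112 of the 255 that fell were listed at 0 in all 3 libraries at 90 mg/L. Such a group was found in 12.0% of all tested unigenes. The 78 called unigenes above 0 in all 9 libraries comprised 21 that rose and 57 that fell. Median log2 differences were 3.25 and -3.24, and 38 of the rises and 76 of the falls had a mean of at least 10 FPKM. The groups did not overlap in 21158 of all tested unigenes (14.3%, against 10% by chance). Relative to the median of all unigenes, higher by 0.22 at 90 mg/L on the log2 scale, 87 rose and 345 fell (median-ratio scaling), so that 20.1% of the calls were rises in place of 29.9%. Leaving out any single library except GBH 60 mg/L replicates 2 and 3 ended the call of Cluster-47276.255942 (adjusted p of 0.0538 to 0.108), as did leaving out the 3 that lie apart (0.122) or a term for the fragment worth index (0.0922), while its log2 difference was 4.99 to 6.07 in these fits against 5.60 with all libraries. In all, Cluster-47276.255942 missed the threshold in 10 of 21 alternatives, with an adjusted p of up to 0.13 by limma. Cluster-47276.169351 had an adjusted p of 0.0569 without the 3 libraries that lie apart and of 0.0585 with a pseudocount of 0.1, at log2 differences of -8.58 and -8.84. The count of 364 became 994 without the 3 libraries that lie apart (2 against 2, with 168 of the 364 called again), 675 with a term for them, 749 without control replicate 2, 554 without GBH 60 mg/L replicate 2, 123 at a mean of at least 5 FPKM, 76 among unigenes above 0 in all libraries and 17 when limma was fitted to these 6 libraries alone. With the replicate number as a block it was 9.

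**Figure D4:**
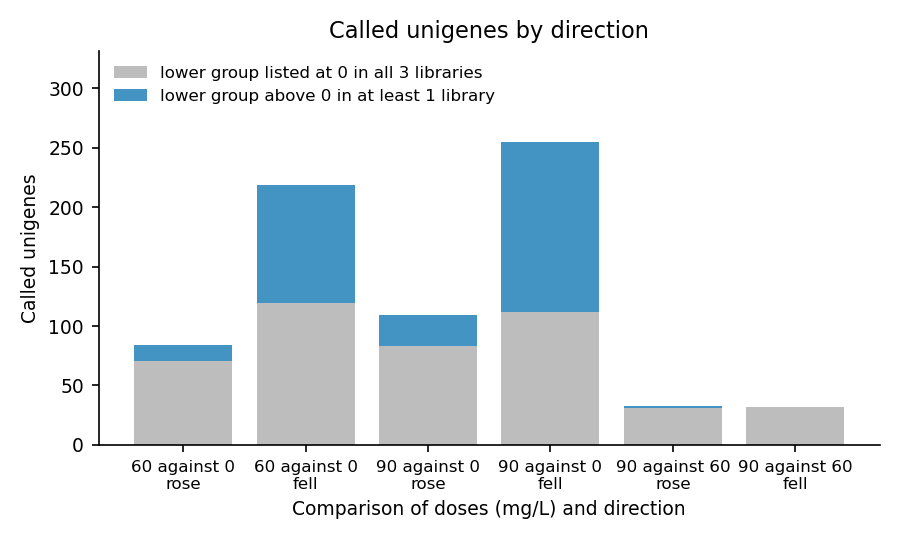
Called unigenes (adjusted p under 0.05, limma) by comparison of doses in mg/L and direction; grey, those whose lower group was listed at 0 in all 3 libraries, and blue, those above 0 in at least 1 library of it. With all 9 libraries falls outnumber rises against control (219 to 84 and 255 to 109), which turned without any single 60 mg/L library for the first comparison and without GBH 90 mg/L replicate 1 or 3 for the second, and between the doses 63 of the 65 calls are grey.

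The response at both doses was compared unigene by unigene. A fall at both doses was found in 196 unigenes and a rise at both in 37 (80 and 74 with a pseudocount of 0.1), and 0 of those called at both doses by limma went in opposite directions. Of the 196, 71 were listed at 0 in all 6 exposed libraries and 125 were above 0 in at least 1 of them. Of the 37, 30 were listed at 0 in all controls. The unigenes called at both doses made up 76.9% of the calls at 60 mg/L and 64.0% of those at 90 mg/L. Their median size was 3.35 at 60 mg/L and 3.33 at 90 mg/L on the log2 scale, and 0 of them passed the test of 90 against 60 mg/L (limma, 5555 of all tested unigenes at an unadjusted p under 0.05). Only 65 of all 147577 tested unigenes passed that test, and a call at both doses favours alike values. These values therefore do not show an equal response at both doses. Independent lists would share 0.0620 rises and 0.378 falls.

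A further 70 unigenes passed the threshold at 60 mg/L and not at 90 mg/L, and 131 at 90 mg/L and not at 60 mg/L, which by itself does not show that the doses differed. Of all calls at either dose 64 passed the test of 90 against 60 mg/L, and 256 of the 303 and 313 of the 364 calls had the same sign at the other dose. Of the 47 that rose with a call at 60 mg/L only, 39 were listed at 0 in every control and every 90 mg/L library. Of the 72 that rose with a call at 90 mg/L only, 40 were listed at 0 in every control and every 60 mg/L library. Over all tested unigenes, 97 stood at 1 FPKM or more in all 3 libraries at 60 mg/L and at 0 elsewhere. At 90 mg/L these were 89, and sets of 3 libraries of any dose ranged from 32 to 351. Such a pattern therefore does not by itself show an effect of 1 dose. Falls with a call at 60 mg/L only numbered 23, and at 90 mg/L only 59. Both comparisons used the same controls, which could not be split into parts of 2 libraries each, so part of the sharing may come from them. Across tested unigenes the log2 differences at both doses correlated at 0.587 (0.500 in 20 simulations of unchanged groups), and unigenes are not independent replicates. The covariance was 0.439 against 0.346 in the simulations, a difference of 0.0923. The simulated noise was independent between libraries and lacked the structure of the 3 libraries that lie apart. Neither difference from the simulations can therefore be taken for a response shared by both doses. The overlap of 233 unigenes became 639 without the 3 libraries that lie apart, 370 with a term for them, 552 without control replicate 2, 154 with a pseudocount of 0.1, 149 with the fragment worth index as a term, 67 at a mean of at least 5 FPKM and 19 among unigenes above 0 in all libraries. With the replicate number as a block the overlap was 0.

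**Figure D5:**
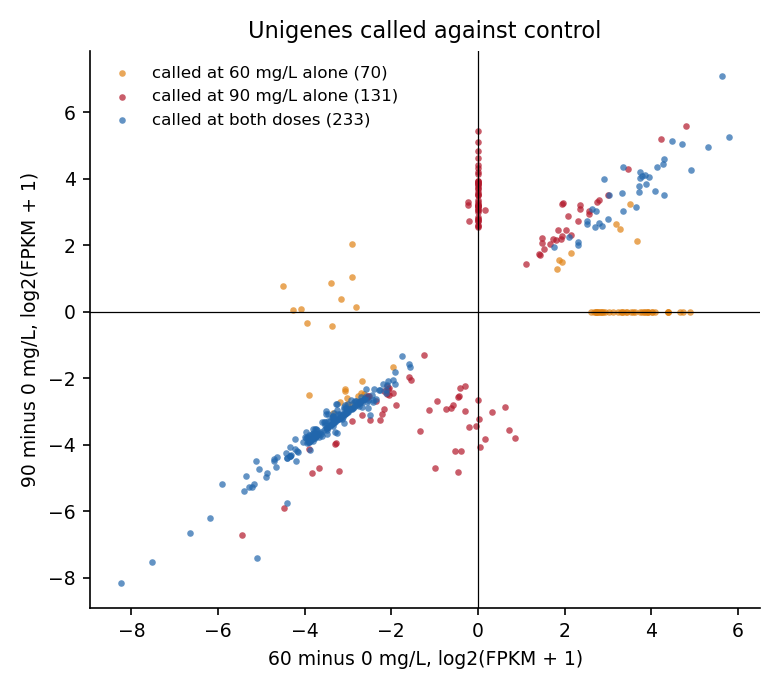
Log2 differences on the log2(FPKM + 1) scale at 60 mg/L (horizontal) and 90 mg/L (vertical) against control, 1 point per called unigene. The 233 unigenes called at both doses lie in the quadrants of equal sign, and unigenes on an axis have a log2 difference of 0 at the other dose.

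Between 90 and 60 mg/L, the comparison that asked whether the response depends on dose, 33 unigenes rose and 32 fell. The even split was lost when a library of either group was left out: falls prevailed without GBH 60 mg/L replicate 1, 2 or 3 (46 rises to 239 falls, 62 to 249 and 40 to 211) and rises without GBH 90 mg/L replicate 1, 2 or 3 (169 to 27, 63 to 32 and 144 to 61). Cluster-47276.224417 was listed at 0 in the controls and at 60 mg/L and stood at 102.87, 52.12 and 13.58 FPKM at 90 mg/L (adjusted p = 0.0384 by limma). Cluster-47276.310816, at 16.01, 20.68 and 30.41 FPKM in controls, was listed at 0 in all 3 libraries at 60 mg/L and stood at 48.04, 38.15 and 30.15 FPKM at 90 mg/L (adjusted p = 0.0134). Cluster-47276.89006 stood at 38.85, 36.51 and 17.07 FPKM at 60 mg/L and was listed at 0 in the other 6 libraries (adjusted p = 0.0137). Cluster-47276.167629 had the same pattern, with 27.68, 39.56 and 14.9 FPKM at 60 mg/L (adjusted p = 0.0177). For Cluster-47276.224417, Cluster-47276.89006 and Cluster-47276.167629 all spread came from the libraries of a single dose, while the fit counted 6 residual degrees of freedom. Their p-values may therefore be too small. A group listed at 0 was found in 31 of the 33 that rose and in all 32 that fell, and 0 of the 65 lay above 0 in all libraries. These 63 calls compare with a median of 74, and at most 115, in the other splits of these 6 libraries. The groups did not overlap in 8858 tested unigenes (6.0%, against 10% by chance). The calls of Cluster-47276.224417, Cluster-47276.89006 and Cluster-47276.167629 were lost at a mean of at least 5 FPKM (adjusted p = 0.288, 0.246 and 0.346) and without control replicate 1 or 3 (adjusted p of 0.0558 to 0.11), and that of Cluster-47276.310816 without control replicate 1 (adjusted p = 0.0518). In all, Cluster-47276.310816 missed the threshold in 2 of 21 alternatives, with an adjusted p of up to 0.167 by limma. Without the 3 libraries that lie apart Cluster-47276.89006 and Cluster-47276.167629 had an adjusted p of 0.0825 and 0.0759, at log2 differences of -4.75 and -4.42 against -4.91 and -4.72 with all libraries. Cluster-47276.224417 also lost its call without control replicate 2, any library at 60 mg/L or GBH 90 mg/L replicate 2 (adjusted p of 0.073 to 0.117), without a filter (0.0586), with a term for the 3 libraries that lie apart (0.0525) and with the fragment worth index as a term (0.0615), at log2 differences of 5.28 to 5.43. Without 1 library at a time, limma called 0 (control replicate 1, with 5356 at an unadjusted p under 0.05), 128 (control replicate 2), 1 (control replicate 3), 285, 311 and 251 (GBH 60 mg/L replicates 1, 2 and 3) and 196, 95 and 205 (GBH 90 mg/L replicates 1, 2 and 3), and 533 without the 3 libraries that lie apart (28 of the 65 called again). The count was 4 at a mean of at least 5 FPKM, 31 with the fragment worth index as a term, 118 without a trend on mean expression, 1 when limma was fitted to these 6 libraries alone and 0 among unigenes above 0 in all libraries (1664 at an unadjusted p under 0.05). With the replicate number as a block limma called 0 (5950 at an unadjusted p under 0.05).

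A test over all 3 doses together found 369 unigenes that differed among them (limma F test, adjusted p under 0.05). As a straight line on dose in mg/L, expression rose in 4 unigenes and fell in 3, while 14519 passed an unadjusted p under 0.05. The number on the line was 297 under median-ratio scaling, 243 under quantile normalization, 122 at a mean of at least 5 FPKM, 198 among unigenes above 0 in all libraries, 462 with a term for the 3 libraries that lie apart and 2 without them. With a pseudocount of 0.1, no filter, no trend on mean expression or a robust spread it was 0 by limma (14611, 26941, 14056 and 14399 at an unadjusted p under 0.05). It was 0 without control replicate 1, 2 or 3, GBH 60 mg/L replicate 3 or GBH 90 mg/L replicate 1 or 2 (11485 to 14009 at an unadjusted p under 0.05 by limma), 12 without GBH 60 mg/L replicate 2 or GBH 90 mg/L replicate 3 and 5 without GBH 60 mg/L replicate 1. The number that differed among the doses was 1268 without the 3 libraries that lie apart, 557 with a term for them, 98 at a mean of at least 5 FPKM, 200 with the fragment worth index as a term, 27 among unigenes above 0 in all libraries, 761 without control replicate 2, 583, 798 and 572 without GBH 60 mg/L replicates 1, 2 and 3, and 600 without GBH 90 mg/L replicate 3. With the replicate number as a block this number and that on the line were both 0.

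The 3 libraries that lie apart hold 1 library of each dose, so the test with 1 mean per dose cannot be made within them. Within the other 6, with 2 libraries per dose, limma called 1098 unigenes at 60 mg/L, 994 at 90 mg/L and 533 between the doses. Among these were 156 of the 303, 168 of the 364 and 28 of the 65 called with all libraries.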

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

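The number of calls changed with many settings. Direction is no measure of stability here, since the groups did not overlap in any of the 303, 364 and 65 called unigenes and many settings reuse the same difference. Under median-ratio scaling 291, 342 and 51 of them were called again, and under quantile normalization 289, 343 and 55. Settings that name the 3 libraries that lie apart, the fragment worth index or unigenes above 0 in all libraries, and every setting for either dose against control, were chosen after seeing the data. Causes were not tested, apart from fewer libraries or unigenes in a fit.

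With the replicate number as a block, limma called 0 unigenes at 60 mg/L (10940 at an unadjusted p under 0.05), 9 at 90 mg/L and 0 between the doses (5950), 0 among the 3 doses (10201), 0 with a trend (14806), an overlap of 0, and 362 for either dose. Pairs of equal number passed the bound of 0.1 for 60 and 0 mg/L (lowest correlation of deviations 0.104), although a pair of unlike number gave 0.134. In the other 2 comparisons pairs of equal number did not pass (lowest -0.173), and 4 of the 9 libraries correlated best with their own number. Whether the numbers pair the libraries is therefore not established. In the order 60 against 0, 90 against 0, 90 against 60, among the 3 doses, trend and overlap, a mean of at least 5 FPKM gave 83, 123, 4, 98, 122 and 67. Leaving out the 3 libraries that lie apart gave 1098, 994, 533, 1268, 2 and 639, and 1678 for either dose. Unigenes above 0 in all libraries gave 20, 76, 0 (1664 at an unadjusted p under 0.05), 27, 198 and 19. A term for the 3 libraries gave 472 at 60 mg/L, 675 at 90 mg/L, 557 among the doses, 462 with a trend, 370 shared and 1459 for either dose. The fragment worth index as a term gave 31 between the doses, 200 among them and 149 shared. A fit to the 2 groups compared gave 0 (9318 at an unadjusted p under 0.05), 17 and 1. The trend count was 0 with a pseudocount of 0.1, no filter, no trend on mean expression or a robust spread (14611, 26941, 14056 and 14399 at an unadjusted p under 0.05), 297 with median-ratio scaling and 243 with quantile normalization. The pseudocount of 0.1 gave 154 shared, and no trend on mean expression 118 between the doses.

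Without 1 library at a time, counts ranged from 262 to 685 at 60 mg/L, 308 to 749 at 90 mg/L, 0 to 311 between the doses (0, 128 and 1 without control replicates 1, 2 and 3, 5356 at an unadjusted p under 0.05 for the 0 by limma, and 95 to 311 without a library of the 2 groups), 255 to 798 among the doses, 0 to 12 for the trend, 168 to 552 for the overlap and 525 to 931 for either dose, the highest of the last without control replicate 2. The surplus of unigenes above 0, 21488 at 60 mg/L and 20531 at 90 mg/L, ranged from 15454 to 29314 and from 13775 to 29492. In the number above 0, exposed and control libraries overlapped. The exact permutation p was 0.2 at each dose (adjusted p = 0.487) and 0.0952 for both doses together (adjusted p = 0.329). The 12 results for named unigenes passed the threshold in 203 of 254 alternatives. Depth was recovered only relative to control replicate 1, and all simulated changes of log2 1 and 2 were missed, so smaller changes are not excluded.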

Other observations

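The comparison of both doses together against control and all tests below were chosen after the results were seen, except those on the gap without the 1000 most abundant unigenes, on the straight line on dose, on the overlap of both doses and on the shift by expression level, which was chosen after the counts of unigenes but before its own values were seen. Against the 3 controls, the 6 exposed libraries differed in 618 unigenes (limma, adjusted p under 0.05), of which 430 fell and 188 rose, with median log2 differences of -2.77 and 2.26. In all 6 exposed libraries 131 of them were listed at 0, and 66 were listed at 0 in all controls. Above 0 in all 9 libraries were 237, of which 145 fell and 92 rose. The share of rises was 30.4%, 16.2% under median-ratio scaling (115 of 711) and 52.2% with a term for the 3 libraries that lie apart (761 of 1459), while 254 rose and 235 fell at a mean of at least 5 FPKM and 344 rose and 419 fell with a pseudocount of 0.1. Without these 3 libraries 1678 unigenes were called, 423 of the 618 among them, and without control replicate 2 the number was 931.

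Other groupings of the libraries were compared with the labels. For 60 against 0 mg/L the labels gave 303 calls and the highest of the other 9 splits 108, for 90 against 0 mg/L 364 and 90, and for 90 against 60 mg/L 65 and 123, where 7 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached (1 of 10 in the first and the second comparison). Of the splits for 60 against 0 mg/L, the 3 others that part all pairs of equal number gave 36, 39 and 42 calls, and those that keep a pair together 24 to 108. Calls above 0 in all libraries numbered 55, 78 and 0 with the labels and at most 1, 4 and 2 in the other splits, and calls with a group listed at 0 numbered 190, 195 and 63 against at most 93, 80 and 115. For the 3 doses, 8 of 100 splits gave at least the 369 calls of the labels, so chance was not excluded. The highest gave 3068, and the 5 drawn splits that made a group of the 3 libraries that lie apart gave 1423 to 3068, which points to a structure of the samples, and 2 others kept the 3 controls together. With a term for these 3, which was chosen from these data, the labels gave 557 calls and 2 of 90 splits as many. The highest other gave 561, the 6 splits that kept the controls together 446 to 561, and the other 84 at most 73. The count thus followed whether the 3 controls stayed together, which they did in 6 of 90 splits. Chance was therefore not excluded at a share of 0.05. For both doses against control, 2 of 84 splits gave at least the 618 calls of the labels. That share is under 0.05 without adjustment for the other groupings tested. The comparison was also chosen after the results were seen, so chance is made less likely and not excluded. The split that set the 3 libraries apart from the rest gave 11256, and the other 82 at most 133. For the overlap of 233, 3 of 100 assignments of doses were as large (highest other 294), again a share without adjustment. For the 7 unigenes on a straight line it was also 3 of 100 (highest other 278). Another on the line, at 11, mixed controls with exposed libraries. Neither result therefore shows an effect of the order of the doses. The 3 drawn assignments that kept the controls at 0 mg/L and mixed both doses gave 294, 250 and 229 shared unigenes, and 278, 2 and 5 on a line. The 7 on a line also became 0 when any 1 of 6 libraries was left out.

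Control replicate 2, GBH 60 mg/L replicate 2 and GBH 90 mg/L replicate 3 were separated from the other 6 libraries on the first component by a gap of 223.0. Depth is argued against as the cause, since 3 of the other 6 libraries had a relative depth within the range of the 3 (0.959 to 1.08) and lay on the far side. Without the 1000 most abundant unigenes the gap was still 221.5, so it does not rest on their own values. The remaining values were not rescaled, so a shift that abundant unigenes impose on all others was not tested and stays open. The 10 highest unigenes held 8.14%, 8.40% and 8.45% of the summed FPKM in the 3, against 7.04% to 7.61% in the other 6. A control among them that was in fact exposed is also argued against, since grouping control replicates 1 and 3 with an exposed library of the 3 gave at most 71 calls where the labels gave 557. On the second component control replicate 2 lay at -165, with the other controls (-217 and -205) and below every exposed library (2.49 to 160). On an axis from control to exposed drawn from the other 6 libraries it scored 70.4, below the exposed libraries of the 3 (153.1 and 156.4). The other controls scored -106.8 and -104.1, but they helped to draw the axis, which moves them outward. That axis therefore cannot tell an ordinary control from 1 with partly exposed-like expression, and the latter is not excluded. The fragment worth index was lowest in the 3 (-0.32, -0.075 and 0, the last tied with control replicate 1) and ordered the other 6 (Spearman rho = -0.886, exact permutation p = 0.0333, Pearson r = -0.875, exact permutation p = 0.0194, 2 relations tested, adjusted p = 0.0333 for both, r = -0.57 without the 2 libraries farthest out, so that the relation rests on those). The 3 lay above the straight line of the other 6 by at least 247.8, but only 1 of them lies within its range, so the bias that the index measures stays open, as may a batch of preparation or a difference between clutches, which the labels do not give, and no biological explanation was tested.

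The exposed libraries held 17762 more unigenes at 1 FPKM or more than the controls. Depth and the bias that the fragment worth index measures are argued against as the whole cause, since the lowest exposed library exceeded the highest control by 12587 among 6 libraries of relative depth 0.95 to 1.1 and by 15794 among 4 with a fragment worth index within 0.05 of 0. A candidate explanation is that abundant unigenes took a larger share of the fragments in controls, which lowers all other FPKM by 1 factor. Without the 1000 most abundant, unigenes above 0 in all libraries were higher in all 6 exposed libraries than in all 3 controls, by 0.45 on the log2 scale at 1 to 2 FPKM and by 0.25 at 10 to 50 FPKM. The difference of 0.20 between both levels overlapped between exposed and control libraries, which neither shows an equal shift nor excludes it, so that such a dilution and a rise of many low unigenes cannot be told apart.

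Cluster identifiers offered a further test. Among the 328 unigenes of the largest cluster family that fell in the 6 exposed libraries against control, 48 lay within 5 identifier numbers of another that fell, against a mean of 5.4 and at most 20 in 1000 draws matched on level and detection (permutation p = 0.001, the smallest these draws can give). Of the 170 that rose, 8 lay near another that rose (mean of draws 1.65, permutation p = 0.00799). None of those that fell, 0, lay near one called as risen (mean of draws 2.89), which argues against reads exchanged between closely numbered unigenes that were both called. An exchange with a partner whose rise was not called is not excluded. Neighbouring numbers may mark pieces or variants of the same transcript, so that the number of independent transcripts behind the calls could be lower than the number of unigenes. Cluster-47276.169351 and Cluster-47276.169348, which both fell at both doses, are 1 such pair.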
